A study of Mus musculus with 14 samples.

How the data were processed

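The starting point was the deposited table of probeset values, which the submitters' processing notes describe as RMA output on the log2 scale. The version of the RMA software and the genome build of the array annotation are not given in the sources used here, so no coordinates are printed. The unit log2 was taken from the deposited notes and no raw scanner intensities were used to check it. All 14 arrays were used and none was left out.

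Of 269751 probesets, 233753 carried 1 gene symbol, 5106 carried several and 30892 were listed with no gene. Only the first kind entered the gene values. Of 23152 symbols, 20875 were found in the RefSeq table of the mouse assembly GRCm38.p6, 2189 were updated through a synonym and 88 were kept as the array gives them. That table served for names and for the order of neighbouring genes alone. The value of a gene was the median of its probesets in each array, with a median of 8 probesets per gene and 2319 genes with a single one. The lowest 25% of genes by mean level, under a log2 level of 4.40, were left out as dim, which took away 5788 genes and left 17364.

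Genes were tested with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8) for reading and with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3 for the figures. The model held 4 group means over all 14 arrays without a block, with 10 residual and 4.06 prior degrees of freedom. The p values were adjusted by the Benjamini-Hochberg method over the 17364 genes of a comparison, and a gene passed at an adjusted p under 0.05. The words rose and fell are used for genes that passed. The interaction is the EGF effect in Cic-/- minus that in Cic+/+.

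The labels give the same clone number to the culture of an animal with EGF and without it, so the arrays are paired by clone. Deviations from the group mean correlated within clone at 0.474, 0.323, 0.459 and 0.337 for clones 1 to 4 and at 0.584, 0.156 and 0.616 for clones 5 to 7, in each case higher than with any other clone. The consensus correlation of the clone block was 0.348.

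Before the data were examined, 29 gene lists were written from general knowledge, and 471 of their 492 members were on the array as 1 gene. The 27 lists with 4 or more measured genes were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists. Camera with an estimated correlation and fry were run beside it. The groups, comparisons, main model and most alternatives were also settled at that point.

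Genes are named by a rule. In each comparison these are the 8 largest rises and 8 largest falls among passing genes whose arrays do not overlap or whose clones all share the sign, leaving out symbols of unnamed or predicted genes such as BC048594, up to 4 passing members of each list and up to 2 not passing where few pass. Cic, Etv1, Etv4, Etv5 and Xist are always eligible. Any other gene is said to have been chosen after its values were seen.

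The alternatives were the mean or the brightest probeset in place of the median, no dim filter or a stricter one at 50%, a trended robust prior, centring or quantile normalization of the arrays, the clone as a random or fixed block, a 1.5-fold minimum, only the arrays compared, each probeset on its own, and leaving out each clone in turn. Restricting the count to genes with concordant probesets, and running camera with the block or with clones left out, were added later.

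The procedure was tested on simulated data with changes added to known genes. For the genotype comparison with EGF it recovered 5.97%, 67.2% and 98.5% of changes of 0.5, 1 and 2 on the log2 scale, with 6 false calls of 120. For the EGF effect in Cic+/+ it recovered 2.99%, 70.1% and 100%, with 1 false call of 116, and with the clone as a block 17.9%, 86.6% and 100%, with 8 false calls of 144. In 20 simulated tables with no change 1 list was called. A list shifted by 0.5 had a camera adjusted p of 1.71e-06. In these tables for the lists every gene varied independently. They do not test camera on lists whose members vary together, such as the mitosis list, with an estimated correlation of 0.872 in the data. Probesets with several symbols or none were left out of the gene values because they cannot be assigned to 1 gene.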

Results

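Gene expression was measured on 14 Affymetrix arrays in neural stem cell cultures taken from the subventricular zone of mice at postnatal day 4. The subventricular zone lines the lateral ventricles, and its stem cells give rise to neurons, astrocytes and oligodendrocytes. Each of 7 cultures, called clones 1 to 7, came from a different animal and had been transduced with an adenovirus carrying Cre recombinase. Clones 1 to 4 kept Cic (Cic+/+) and clones 5 to 7 had lost it (Cic-/-). Cic encodes capicua, a DNA-binding repressor that is relieved by growth factor signalling through ERK. Every clone was kept for 24 h with EGF and for 24 h without it, which gave 4 arrays in each Cic+/+ group and 3 in each Cic-/- group.

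The arrays were alike in scale, with medians from 6.49 to 6.54 on the log2 scale and correlations between arrays from 0.933 to 0.984. Their number limits the precision. The first principal component held 29.7% of the variance. On the second component every Cic+/+ array lay above 0 and every Cic-/- array below it. Clone 4 stood apart by sex. Its Xist level, which marks the inactive X chromosome of female cells, was 4.73 with EGF and 3.83 without, against 11.96 to 12.57 in the 12 arrays of the other clones. In the same clone the Y-linked genes Eif2s3y, Kdm5d and Uty lay between 7.997 and 8.929. The Cic-/- group thus held no clone with the Xist level of clone 4. In what follows, a change is given as log2 ± SE from the limma fit, and a group level as the log2 mean ± SD.

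Cic itself was lower in every Cic-/- array than in any Cic+/+ array. With EGF its level was 9.42, 9.41, 9.69 and 9.50 in clones 1 to 4, and 7.55, 7.67 and 7.40 in clones 5 to 7. Without EGF it was 9.18, 9.31, 9.57 and 9.64 in clones 1 to 4, and 7.27, 7.48 and 7.04 in clones 5 to 7. The change was -1.97 ± 0.15 with EGF (3.91-fold, adjusted p = 2.18e-05) and -2.16 ± 0.15 without (4.48-fold, adjusted p = 9.46e-06). EGF did not move it detectably, with 0.08 ± 0.14 in Cic+/+ (adjusted p = 0.883) and 0.27 ± 0.16 in Cic-/- (adjusted p = 0.664).

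The array carries 23 probesets of Cic, each a group of probes within 1 stretch of the transcript. Of these, 13 were lower in both media, 3 passed in 1 medium and 7 in neither, adjusted over the 23. The fall was steepest at 3 neighbouring probesets. At probeset 17475211 it was -7.01 ± 0.39 with EGF and -7.40 ± 0.39 without, at 17475209 -4.60 and -4.49, and at 17475210 -3.14 and -3.31. The Cic-/- means at 17475211, 3.13 and 2.85, lie under the limit of 4.40 used for dim genes, so the size of that fall is not exact. Clone 6 lay below the other Cic-/- clones at most of the probesets before these, though not at 17475194 or 17475203. At 17475202 it lay at -2.83 from the Cic+/+ mean over both media, against 0.08 in clone 5 and -0.55 in clone 7, and at 17475208 at -1.13, against 1.53 and 0.91. After them it lay above the others from 17475214 to 17475223, at 17475216 at -1.32 against -2.44 and -2.21. Which exons the engineered allele removes is not given in the sources used here, so probesets outside the deleted part check nothing about the deletion.

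**Figure D1:**
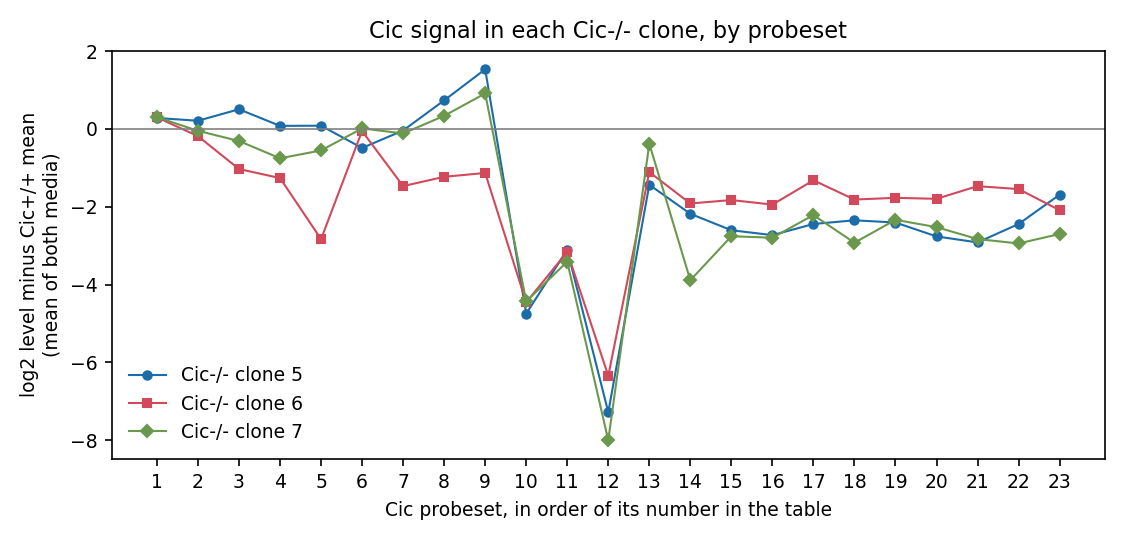
Log2 change of each of the 23 Cic probesets in the Cic-/- clones relative to the Cic+/+ mean, in table order. The 3 probesets in the middle fall steeply in all 3 clones, while at 17475202 and 17475208 before them clone 6 lies below clones 5 and 7, and at 17475216 after them above.

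The first comparison asks what loss of Cic changes in cells growing with EGF. Pdgfra, the PDGF receptor that marks oligodendrocyte progenitors, fell from 10.15 ± 0.24 in Cic+/+ (n = 4) to 7.54 ± 0.82 in Cic-/- (n = 3), a change of -2.61 ± 0.38 or 6.09-fold (adjusted p = 0.0082). Ajap1, a component of adherens junctions, fell to 4.85 ± 0.65 (-3.53 ± 0.45, adjusted p = 0.0032). Unc93b1, which carries Toll-like receptors to endosomes, fell 4.31-fold (-2.11 ± 0.28, adjusted p = 0.00452). The clustered protocadherins Pcdhb2 and Pcdhb3, cell adhesion molecules of neural cells, rose 4.09-fold (2.03 ± 0.22, adjusted p = 0.00077) and 2.82-fold (1.495 ± 0.19, adjusted p = 0.00337). In all, 55 of 17364 genes passed, 13 higher and 42 lower, and in all 55 the arrays of the genotypes did not overlap, which a passing test nearly ensures. Over all genes 11.7% showed no overlap, where chance gives 5.71%.

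BC048594, an unnamed gene noted here after its values were seen, rose from 3.76 ± 0.45, a level under the dim limit, to 7.47 ± 0.22 (adjusted p = 1.85e-05). Among the named rises were also Megf10, an engulfment receptor (1.80 ± 0.33), the collagen receptor Mrc2 (1.48 ± 0.27), Npvf (1.06 ± 0.19), Mir139 (1.04 ± 0.14, from a single probeset), Tmem242 (0.93 ± 0.15) and Dysf, which acts in membrane repair (0.87 ± 0.16). Erdr1 fell by 2.23 ± 0.20 on the log2 scale, with all 5 probesets below -1. The gene values of Dad1, Rps13 and Eif2s2 were also lower (-3.08 ± 0.23, -2.13 ± 0.22 and -1.95 ± 0.26), but in each of them only 1 probeset lay below -1, of 7, 2 and 4. Those single probesets lay at -5.00, -4.69 and -4.33. By contrast 16 of 17 Pdgfra probesets and 7 of 8 Ajap1 probesets lay below -1. Pdgfra, Ajap1, Unc93b1, Erdr1, Pcdhb2, Pcdhb3 and Mir139 were among the 10 of 17 named genes that passed whichever clone was left out. The others lost their call, Megf10 without clone 2, 3, 4, 5 or 7 (adjusted p up to 0.133, without clone 7) and Mrc2 without clone 2, 3, 4, 5 or 6 (up to 0.141, without clone 6). Npvf lost it without any 1 clone (up to 0.148, without clone 6), Tmem242 without clone 2, 5, 6 or 7 (up to 0.0805, without clone 5) and Dysf without any clone but clone 1 (up to 0.153, without clone 6). With the brightest probeset in place of the median, 66 genes passed, 21 of them among the 55. Megf10, Mrc2, Tmem242, Dad1 and Ugt8a then lost their call, with adjusted p from 0.113 for Tmem242 to 0.628 for Ugt8a, and Dysf and Eif2s2 turned sign, to -0.17 and 0.55.

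**Figure D2:**
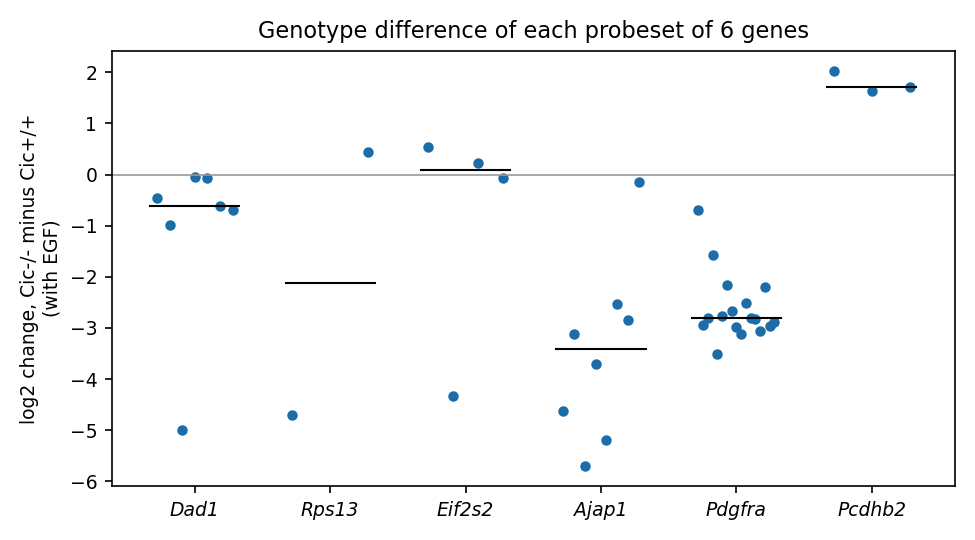
Log2 change between genotypes with EGF of each probeset of Dad1, Rps13, Eif2s2, Ajap1, Pdgfra and Pcdhb2, with a line at the median of each gene's probesets. In Dad1, Rps13 and Eif2s2 a single probeset lies far below the others, while 16 of 17 Pdgfra probesets, 7 of 8 Ajap1 probesets and all 3 Pcdhb2 probesets move together.

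Oligodendrocyte progenitor genes were lower as a group with EGF. Of 15 measured, 1 fell over all genes tested and 4 adjusted over the list alone, with a median of -0.17, lower in 3 of 3 Cic-/- clones (camera adjusted p = 0.00282; adjusted p = 0.492 with an estimated correlation). Of 12 myelinating oligodendrocyte genes, 1 fell, Ugt8a, which makes the myelin lipid galactosylceramide (-1.34 ± 0.24, adjusted p = 0.0334), and 2 adjusted over the list alone. Ugt8a no longer passed on leaving out any of the 7 clones, with an adjusted p up to 0.139 without clone 6. Gsx1, a homeobox gene of the ventral forebrain, fell by 1.03 ± 0.17 on the log2 scale (adjusted p = 0.022; up to 0.118, without clone 7, on leaving out any clone but clone 3), as the 1 passing member of 15 regional identity genes of the subventricular zone.

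Cell cycle genes lay lower in Cic-/- without a single member passing over all genes tested by limma. In the mitosis list, 0 of 26 passed, 13 had an unadjusted p under 0.05 and 10 fell adjusted over the list alone. Its median was -0.89, with 26 of 26 members negative (camera adjusted p = 2.81e-14; adjusted p = 0.492 with an estimated correlation). In the DNA replication list, 0 of 29 passed, 0 adjusted over the list alone and 11 at an unadjusted p under 0.05, with a median of -0.74 (camera adjusted p = 3.06e-11; adjusted p = 0.492 with an estimated correlation). Ccnb2, a mitotic cyclin, was at -0.88 ± 0.42 and the replication helicase gene Mcm2 at -1.03 ± 0.51. Clone 5 contributed most, with a mitosis level of 7.46 against 8.58 and 8.52 in clones 6 and 7 and 8.74 to 9.42 in the Cic+/+ clones. The DNA replication level was 6.81 in clone 5, while clones 6 and 7, at 8.16 and 8.07, lay within the Cic+/+ range of 7.84 to 8.79. Without clone 5 the camera adjusted p was 1.15e-05 for mitosis and 0.0046 for DNA replication.

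Of the other lists, interferon response genes lay lower (median -0.28, 0 of 19 passed, 1 with the clone as a block, and 3 fell adjusted over the list alone, camera adjusted p = 0.00282; adjusted p = 0.492 with an estimated correlation). At an unadjusted p under 0.05 there were 4 of them. Neural stem cell and radial glia genes lay lower by a median of -0.18, with 0 of 20 passing, 2 adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0196; adjusted p = 0.492 with an estimated correlation; 0.0748, 0.122 and 0.0814 without clones 3, 6 and 7). Extracellular matrix and mesenchymal genes lay higher by a median of 0.22, with 0 of 16 passing, 3 higher and 1 lower adjusted over the list alone and, at an unadjusted p under 0.05, 4 higher and 1 lower (camera adjusted p = 0.0115; adjusted p = 0.494 with an estimated correlation; 0.0538 and 0.144 without clones 2 and 7). For EGF receptor family genes the median was 0.32, with 0 of 12 passing, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0271; adjusted p = 0.473 with an estimated correlation; 0.0538, 0.148 and 0.116 without clones 2, 5 and 6). The other 20 lists did not pass, with camera adjusted p from 0.184 to 0.91.

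Genes reported elsewhere as CIC targets, a list drawn from other systems, did not move together with EGF. Of 19, 0 passed, 0 adjusted over the list alone and 3 had an unadjusted p under 0.05, with a median of 0.09 (camera adjusted p = 0.792). The ETS factors Etv1, Etv4 and Etv5 were at -0.07 ± 0.29, 0.27 ± 0.34 and 0.26 ± 0.19, and the ERK feedback regulators Spry1 and Spry2 at -0.34 ± 0.21 and -0.23 ± 0.12, none of them passing. Atxn1, a binding partner of CIC, was at 0.91 ± 0.19 (adjusted p = 0.072), and it passed with the brightest probeset (1.02, adjusted p = 0.0295) and with the mean over probesets (0.96, adjusted p = 0.0146). The count of 55 was 52 without clone 1, and 21, 32, 25, 24, 33 and 26 without clones 2, 3, 4, 5, 6 and 7. With each array centred on its median, 19 genes were higher and 37 lower.

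The second comparison asks the same of cells kept 24 h without EGF, where genes of myelinating oligodendrocytes were lower in Cic-/-. Enpp6, a phosphodiesterase of newly formed oligodendrocytes, was at 8.51 ± 0.13 in Cic+/+ (n = 4) and 4.56 ± 0.49 in Cic-/- (n = 3), a change of -3.95 ± 0.21 (adjusted p = 2.96e-07). The myelin genes Cldn11 and Mbp fell 5.71-fold and 5.09-fold (-2.51 ± 0.26 and -2.35 ± 0.32, adjusted p = 0.000208 and 0.00256), and Mag fell from 6.89 ± 0.41 to 4.33 ± 0.39 (-2.57 ± 0.26, adjusted p = 0.000208). The Cic-/- level of Mag lies under the limit of 4.40 used for dim genes and that of Enpp6 close to it, so the sizes of these changes are not exact. Of the 12 measured genes of this list, 6 fell over all genes tested and 6 adjusted over the list alone. The others were Ugt8a (-2.27 ± 0.24) and Myrf (-1.77 ± 0.21), the transcription factor that drives myelin genes, named here after their values were seen. The list median was -1.21, lower in 3 of 3 Cic-/- clones (camera adjusted p = 4.01e-13; adjusted p = 0.00118 with an estimated correlation). With the brightest probeset in place of the median, Mag did not pass (adjusted p = 0.143). No such value is given here for Ugt8a and Myrf. Between genotypes with EGF, Ugt8a shrank to -0.29 with the brightest probeset (adjusted p = 0.628).

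**Figure D3:**
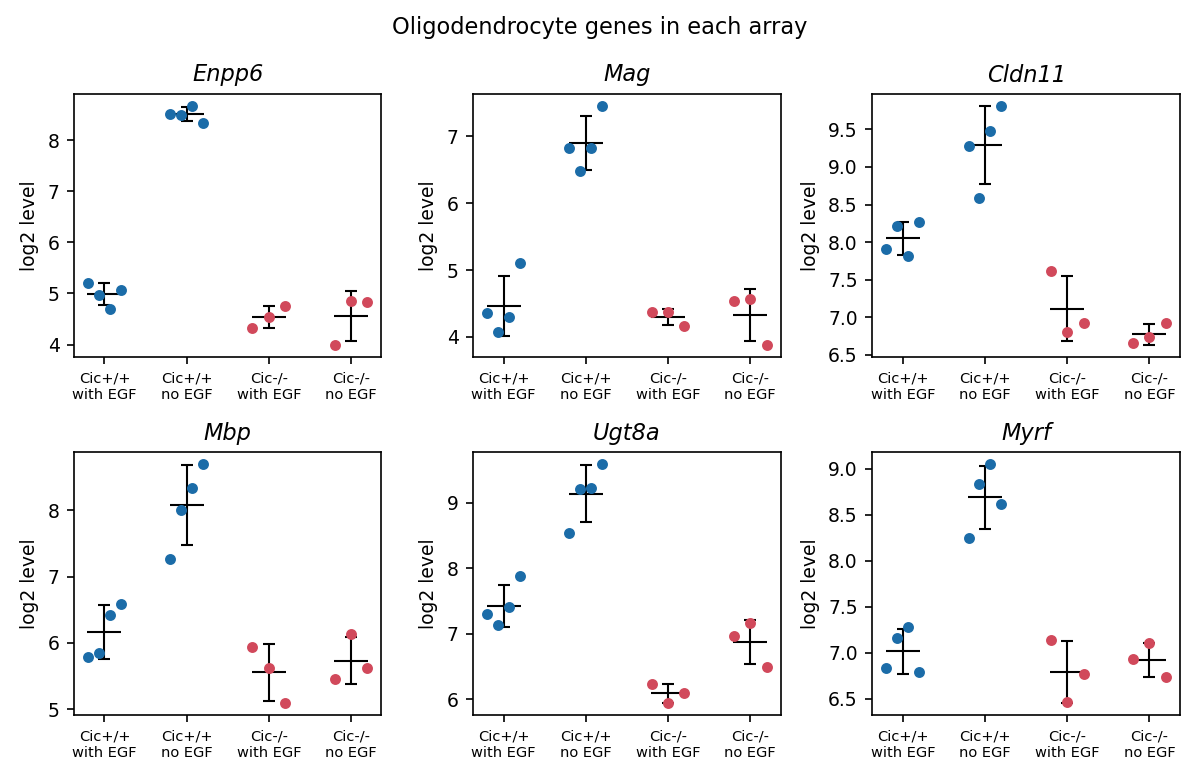
Log2 level of Enpp6, Mag, Cldn11, Mbp, Ugt8a and Myrf in each array of the 4 groups, with the mean and SD in black. Without EGF all 4 Cic+/+ arrays lie above all 3 Cic-/- arrays in each of these genes, and Enpp6 is at 8.51 ± 0.13 against 4.56 ± 0.49.

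Other genes fell as well. Id3 and Id2, inhibitors of bHLH factors that respond to BMP, were at -1.58 ± 0.24 (adjusted p = 0.00683) and -1.07 ± 0.21 (adjusted p = 0.0302; up to 0.119, without clone 6, on leaving out clone 1, 2, 3, 4 or 6). They were the 2 falling members of 15 Hedgehog, Wnt and BMP response genes, of which 3 fell adjusted over the list alone (median -0.08, camera adjusted p = 0.286). Cdkn1c, a cyclin-dependent kinase inhibitor, was at -1.66 ± 0.34 (adjusted p = 0.048; up to 0.167, without clone 5, on leaving out any clone but clone 1). It was the 1 passing member of 20 FoxO target and quiescence genes. F2rl1, a protease-activated receptor, was at -3.22 ± 0.65 (adjusted p = 0.041; up to 0.125, without clone 5, on leaving out any clone but clone 3). Ugt1a6a fell from a single probeset, to 2.95 ± 1.80, far under the dim limit, so its change of -5.05 ± 0.93 is not exact (adjusted p = 0.0244; up to 0.1, without clone 5, on leaving out clone 1, 4, 5 or 7). Ajap1 again fell (-3.53 ± 0.45), to 4.17 ± 0.22, which is under the dim limit, and Dad1 and Rps13 were again lower at 1 probeset each, at -5.27 and -5.10.

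Among the rises, Gstt1, a glutathione transferase, was 5.83-fold higher (2.54 ± 0.33, adjusted p = 0.00148), with 8 of 11 probesets above 1. The secreted BMP and Wnt inhibitor Sostdc1 rose 5.70-fold (2.51 ± 0.44, adjusted p = 0.0179; 0.0603, 0.0806 and 0.0851 without clones 4, 5 and 6) and Wnt5a, a non-canonical Wnt ligand, 3.29-fold (1.72 ± 0.29, adjusted p = 0.011). Ptpn5, a neuronal tyrosine phosphatase, rose by 1.97 ± 0.29, and Pcdhb2 and Pcdhb3 by 2.08 ± 0.22 and 1.59 ± 0.19. Prmt8 (1.78 ± 0.33) and Adamts16 (1.45 ± 0.25) rose too. Prmt8 lay under or at the dim limit in the other 3 groups, and it lost its call without clone 2, 3, 4, 5 or 6 (adjusted p up to 0.0976, without clone 6) and Adamts16 without clones 5 and 6 (0.0798 and 0.0553). Cd24a, a surface protein of neuroblasts, rose by 1.33 ± 0.20 (adjusted p = 0.0069), the 1 of 21 neuroblast and neuron genes that passed, and 2 rose adjusted over the list alone. That list had a median of 0.15 (camera adjusted p = 0.0374; adjusted p = 0.256 with an estimated correlation), and lost its call without clone 1, 2, 3, 5 or 6 (up to 0.0835, without clone 2). Atxn1 rose 1.95-fold (0.96 ± 0.19, adjusted p = 0.0395), a call lost without clone 2, 3, 5, 6 or 7 (up to 0.131, without clone 5). Notch2, at 1.06 ± 0.24, passed with the clone as a block (adjusted p = 0.0447) and not without it (0.0727).

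Of 19 genes reported elsewhere as CIC targets, 0 passed by limma without EGF, 1 rose adjusted over the list alone and 5 had an unadjusted p under 0.05, with a median of 0.06 (camera adjusted p = 0.17). That member was Etv1, at 1.39 ± 0.29 (adjusted p = 0.0504 over all genes). It passed with centred arrays (adjusted p = 0.0331), quantile normalization (0.0401), the trended prior (0.0461) and the stricter dim filter (0.0498), and without clone 4 (0.0394). It did not pass in the other alternatives, at 0.67 with the mean over probesets (0.0972), at 0.28 with the brightest probeset (0.443), and with 0.163 without clone 5. Etv4 was at 0.06 ± 0.34 and Etv5 at 0.41 ± 0.19. DNA replication and mitosis genes had medians of -0.38 and -0.40, with 0 of 29 and 0 of 26 passing, 0 adjusted over the list alone, and 3 and 2 at an unadjusted p under 0.05. Camera gave an adjusted p of 0.0014 for both, and adjusted p = 0.753 with an estimated correlation for both. Without clone 5, whose mitosis level was 7.24 against 8.68 and 8.88 in clones 6 and 7, the camera adjusted p was 0.383 for DNA replication and 0.484 for mitosis.

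Target genes of p53 lay lower by a median of -0.25, with 0 of 16 passing, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0081; adjusted p = 0.631 with an estimated correlation; 0.0763 without clone 3). Astrocyte genes had a median of -0.31, with Id2 the 1 falling member of 17 and 1 adjusted over the list alone (camera adjusted p = 0.0447; adjusted p = 0.631 with an estimated correlation), a call lost without clone 2, 3, 4, 6 or 7 (up to 0.169, without clone 7). Interferon response genes had a median of -0.25, with 0 of 19 passing, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0447; adjusted p = 0.753 with an estimated correlation), a call lost without clone 2, 3, 4, 5 or 7 (up to 0.212, without clone 4). Oligodendrocyte progenitor genes had a median of -0.04, with 0 of 15 passing, 1 higher and 3 lower adjusted over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.291; adjusted p = 0.753 with an estimated correlation; 0.0118 by camera at the preset correlation without clone 6). Pdgfra was at -0.55 ± 0.38 (adjusted p = 0.654), and its difference from the change with EGF did not pass (adjusted p = 1).

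Without EGF 96 genes passed, 22 higher and 74 lower, and 9.38% of all genes showed no overlap of the genotypes' arrays. Of these, 29 also passed with EGF, 5 higher and 24 lower, where 0.0165 and 0.179 would be shared by independent lists of these sizes. The same clones were measured in both media, so these are not independent. In 20 simulated tables with clone effects and no effect of genotype, the highest shared count was 0. The clone effects there had the same strength in every gene, and the 2 genotype effects correlated at a median of 0.349, against 0.629 in the data. The simulation therefore cannot tell an effect of Cic from stronger differences between the animals that repeat in both media. With centred arrays 40 genes were higher and 71 lower. With the brightest probeset 72 genes passed, 32 of them among the 96, and Ptpn5, Adamts16, F2rl1, Dad1, Mag, Atxn1, Cd24a and Cdkn1c lost their call, with adjusted p from 0.0601 for Atxn1 to 0.752 for Adamts16. Of these F2rl1 and Atxn1 stayed close to their size, at -2.99 and 0.85. Without clone 5 there were 63 genes, and without clone 3 or clone 5 the number of lists passing by camera was 3 rather than 7, and 4 without clone 2.

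The next comparison asks what EGF changes in Cic+/+ cells, with genes of mature glia lower in its presence. Enpp6 fell with EGF from 8.51 ± 0.13 to 4.99 ± 0.21 (-3.52 ± 0.19, adjusted p = 4.97e-07, n = 4 clones). Fa2h, a fatty acid hydroxylase of myelin lipids, fell 7.32-fold (-2.87 ± 0.27, adjusted p = 0.000268; 0.19 with the brightest probeset, the opposite sign) and Gpr17, a receptor of late progenitors, 6.54-fold (-2.71 ± 0.29, adjusted p = 0.000536), while Mag fell to 4.46 ± 0.45, close to the dim limit (-2.43 ± 0.24, adjusted p = 0.000364). Dgkk, a diacylglycerol kinase, rose 6.14-fold (2.62 ± 0.33, adjusted p = 0.00188) and Pkig, an inhibitor of protein kinase A, 3.42-fold (1.77 ± 0.22, adjusted p = 0.00166). In all, 156 genes passed, 53 higher and 103 lower, each in the same direction in 4 of 4 clones. Over all genes 28.9% shared the sign in the 4 clones, where chance gives 12.5%.

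Of 12 myelinating oligodendrocyte genes, 6 fell and 7 adjusted over the list alone (median -1.18, lower in 4 of 4 clones, camera adjusted p = 2.71e-13; adjusted p = 0.00112 with an estimated correlation). Mbp was at -1.92 ± 0.30 (adjusted p = 0.00734; 0.0963 and 0.0722 without clones 2 and 3) and Ugt8a at -1.71 ± 0.22 (adjusted p = 0.00259; 0.0643 without clone 2). Of 17 astrocyte genes, 4 fell and 9 adjusted over the list alone (median -0.79, lower in 4 of 4 clones, camera adjusted p = 1.25e-10; adjusted p = 0.0125 with an estimated correlation). The 4 were the water channel Aqp4 (-2.28 ± 0.32), S100b (-2.14 ± 0.44), Clu (-1.29 ± 0.18) and the gap junction gene Gja1 (-0.88 ± 0.15). Aqp4 lost its call without clone 2 (adjusted p = 0.0731), Clu without clones 2 and 4 (0.0661 and 0.0538), Gja1 without clone 2, 3 or 4 (up to 0.0968, without clone 4) and S100b without any 1 clone (up to 0.312, without clone 2). Of 15 oligodendrocyte progenitor genes, Gpr17 and Neu4 (-1.04 ± 0.21; adjusted p = 0.0315; up to 0.236, without clone 2, on leaving out clone 2, 3 or 4) fell, and 5 adjusted over the list alone (median -0.47, camera adjusted p = 2.63e-05; adjusted p = 0.146 with an estimated correlation).

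Of 16 target genes of p53, 1 rose and 6 adjusted over the list alone (median 0.35, higher in 4 of 4 clones, camera adjusted p = 2.09e-07; adjusted p = 0.112 with an estimated correlation). That gene was Cdkn1a, a cyclin-dependent kinase inhibitor (1.09 ± 0.19, adjusted p = 0.0148; 0.101 and 0.12 without clones 2 and 4). Cdkn1c fell by 1.72 ± 0.32 on the log2 scale (adjusted p = 0.0202; 0.168 and 0.184 without clones 2 and 4). DNA replication genes had a median of 0.54, with 29 of 29 positive, 0 passing, 0 adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 2.09e-07; adjusted p = 0.487 with an estimated correlation). Mitosis genes had a median of 0.40, with 0 of 26 passing, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.000387; adjusted p = 0.663 with an estimated correlation). Ribosome biogenesis and MYC target genes had a median of 0.39, with 0 of 22 passing, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.00164; adjusted p = 0.663 with an estimated correlation).

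Lists of genes downstream of EGF signalling lay higher with it, and the receptor family lay lower. Genes reported elsewhere as CIC targets had a median of 0.27, higher in 4 of 4 clones, with 0 of 19 passing by limma, 2 adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.00406; adjusted p = 0.0783 with an estimated correlation). With the clone as a block 3 of them passed. ERK output genes had a median of 0.34, with 0 of 15 passing, 3 higher and 1 lower adjusted over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.029; adjusted p = 0.12 with an estimated correlation; 0.0815 and 0.0523 without clones 2 and 3). Immediate early genes had a median of 0.34, with 0 of 17 passing, 4 adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.000621; adjusted p = 0.127 with an estimated correlation). Etv1, Etv4 and Etv5 were at 0.36 ± 0.27, -0.37 ± 0.32 and 0.34 ± 0.18. EGF receptor family genes had a median of -0.24, with 0 of 12 passing, 1 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0241; adjusted p = 0.112 with an estimated correlation; 0.0674 without clone 1). Egfr was at -0.23 ± 0.19.

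Cholesterol synthesis genes had a median of 0.15, with 0 of 19 passing, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0428; adjusted p = 0.672 with an estimated correlation; 0.0507 and 0.293 without clones 3 and 4). The other 15 lists did not pass, with camera adjusted p from 0.0547 to 0.999. Further named genes were Pla2g7, an enzyme that degrades platelet-activating factor (-3.17 ± 0.42), the exchanger Slc24a3 (-2.46 ± 0.45), Tuba4a (-2.27 ± 0.47), Cpne7 (2.05 ± 0.36), the fibrillin gene Fbn2 (1.98 ± 0.37), the secreted factor Angptl2 (1.84 ± 0.33), Cacng5 (1.79 ± 0.34), the axon guidance ligand Sema3a (1.77 ± 0.26), Znrf2 (1.69 ± 0.34), the gelatinase Mmp2 (0.96 ± 0.19) and the purine salvage gene Hprt (1.14 ± 0.21). These 11 lost their call on leaving out clone 2, with adjusted p from 0.0661 for Pla2g7 to 0.283 for Znrf2. All but Pla2g7 and Sema3a also lost it without clone 3 (0.195 for Cacng5), all but these and Cacng5 without clone 4 (0.167 for Hprt), and Tuba4a and Mmp2 without clone 1 (0.0974 and 0.0773).

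Clone 2, 3 or 4 alone moved the count of 156 genes, to 17, 34 and 38 without them, against 147 without clone 1. With the clone as a block, which compares the media within each animal, 897 genes passed, 342 higher and 555 lower, and all 156 were among them. Of the lists above it called 7 myelinating oligodendrocyte, 9 astrocyte, 5 progenitor, 5 p53, 4 immediate early, 3 higher and 1 lower ERK output and 2 lower EGF receptor family genes, where limma without it called 6, 4, 2, 1, 0, 0 and 0. With the brightest probeset 108 genes passed, 59 of them among the 156. Cpne7, Cacng5, Pkig, Mag, Tuba4a, Neu4, Ugt8a, Cdkn1c and Mmp2 then lost their call, with adjusted p from 0.0526 for Tuba4a to 0.667 for Cacng5, though Tuba4a, Cpne7 and Mmp2 were at larger sizes than before, -2.64, 2.56 and 1.58. Neu4 stayed close to its size, at -0.94, while Cacng5 and Ugt8a shrank to 0.20 and -0.31. The block brought in the intermediate filament gene Nes (1.32 ± 0.40, adjusted p from 0.16 to 0.0226), Epha2 (1.08 ± 0.33, from 0.161 to 0.0288), Pecam1 (0.57 ± 0.16, from 0.113 to 0.0187) and Atxn1 (-0.64 ± 0.18, from 0.127 to 0.0291). This was the random block. With the clone as a fixed block Atxn1 did not pass, and Dcx did (-1.22, adjusted p = 0.0142).

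The same comparison in Cic-/- cells asks how they respond to EGF. Dgkk rose 6.18-fold with EGF (2.63 ± 0.38, adjusted p = 0.0151, n = 3 clones) and Angptl2 5.73-fold (2.52 ± 0.38, adjusted p = 0.0151). Gpr17 fell 5.50-fold (-2.46 ± 0.34, adjusted p = 0.013), Pla2g7 6.57-fold (-2.72 ± 0.48, adjusted p = 0.0409) and Tmem255b 4.45-fold (-2.15 ± 0.26, adjusted p = 0.00419). In all, 33 genes passed, 17 higher and 16 lower, each in the same direction in 3 of 3 clones. Over all genes 36.8% shared the sign in the 3 clones, where chance gives 25%. The taurine transporter gene Slc6a6, the integrin gene Itga4, Kcnip1, Kcnmb1, the muscarinic receptor gene Chrm3 and Psrc1 rose, by 1.95 ± 0.30, 1.85 ± 0.29, 1.79 ± 0.26, 1.601 ± 0.24, 1.56 ± 0.29 and 1.51 ± 0.23. Khdrbs2, Dpp10, Sncaip, Sh3bp4 and Mapk8ip2 were at -2.40 ± 0.28, -2.20 ± 0.35, -1.74 ± 0.26, -1.62 ± 0.23 and -1.47 ± 0.20. With the brightest probeset 22 genes passed, 9 of them among the 33, and Mapk8ip2 turned sign, to 0.11. Itga4, Kcnip1, Kcnmb1, Psrc1, Pla2g7, Khdrbs2, Dpp10, Sncaip and Sh3bp4 then lost their call, with adjusted p from 0.0615 for Pla2g7 to 0.996 for Kcnmb1. Itga4 was at a larger size than before, 2.37, while Kcnmb1 and Khdrbs2 shrank to 0.00998 and -0.35. All 16 named genes lost their call without clone 5, with adjusted p up to 0.19 for Chrm3, and without clone 6, from 0.139 for Tmem255b to 0.588 for Chrm3. Without clone 7, Angptl2, Slc6a6, Kcnip1, Kcnmb1, Chrm3, Psrc1, Dpp10 and Sncaip lost it (up to 0.109, for Chrm3).

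Of 15 oligodendrocyte progenitor genes, 1 fell in Cic-/-, Gpr17, and 7 adjusted over the list alone (median -0.64, lower in 3 of 3 clones, camera adjusted p = 3.34e-10; adjusted p = 0.063 with an estimated correlation). Pdgfra was at -1.80 ± 0.41 (adjusted p = 0.0938; 0.00978 with the clone as a block). Of 16 target genes of p53, 0 passed by limma, 12 rose adjusted over the list alone and 13 had an unadjusted p under 0.05 (median 0.76, higher in 3 of 3 clones, camera adjusted p = 2.16e-14; adjusted p = 0.063 with an estimated correlation). With the clone as a block 7 of them passed, among them Cdkn1a (1.12 ± 0.22, adjusted p from 0.0518 to 0.00518). Of 17 astrocyte genes, 0 passed, 5 fell adjusted over the list alone and 7 had an unadjusted p under 0.05 (median -0.48, lower in 3 of 3 clones, camera adjusted p = 5.52e-06; adjusted p = 0.063 with an estimated correlation). Of these Aqp4 was at -1.72 ± 0.37 (adjusted p = 0.0758; 0.00713 with the block). The neuroblast microtubule gene Dcx was at -2.74 ± 0.54 (adjusted p = 0.0518; 0.00393 with the block), and the endothelial cadherin gene Cdh5 at 1.06 ± 0.27 (adjusted p = 0.153; 0.0413 with the block). Cdh5 without EGF was at 3.99 ± 0.40, under the dim limit, so its change is not exact. With the clone as a fixed rather than a random block Cdh5 did not pass, and the p53 target Mdm2 did (0.72, adjusted p = 0.0385).

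Extracellular matrix and mesenchymal genes had a median of 0.59, with 16 of 16 positive, 0 passing, 1 adjusted over the list alone and 5 at an unadjusted p under 0.05 (camera adjusted p = 5.52e-06; adjusted p = 0.186 with an estimated correlation). ERK output genes had a median of 0.32, with 0 of 15 passing, 1 adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0294; adjusted p = 0.125 with an estimated correlation; 0.134 without clone 6). Immediate early genes had a median of 0.33, with 0 of 17 passing, 2 adjusted over the list alone and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.0423; adjusted p = 0.379 with an estimated correlation; 0.592 without clone 5). Ribosome biogenesis and MYC target genes had a median of 0.37, with 0 of 22 passing, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0258; adjusted p = 0.776 with an estimated correlation; 0.686 without clone 6). Genes reported elsewhere as CIC targets had a median of 0.10, with 0 of 19 passing, 2 higher and 1 lower adjusted over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.206). Of 12 myelinating oligodendrocyte genes, 0 passed, 0 adjusted over the list alone and 4 had an unadjusted p under 0.05, with a median of -0.08 (camera adjusted p = 0.598).

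With the clone as a block 361 genes passed, 174 higher and 187 lower, with all 33 among them. Of the lists above it called 5 progenitor, 3 astrocyte, 1 extracellular matrix, 1 ERK output, 2 immediate early and 2 CIC target genes, where limma without it called 1, 0, 0, 0, 0 and 0. Leaving out clone 5 or clone 6 left 0 genes by limma, with 1451 and 1043 at an unadjusted p under 0.05, and leaving out clone 7 left 18. Of the 33 genes, 17 had also passed in Cic+/+, 11 higher and 6 lower in both, where 0.0519 and 0.0949 would be shared by independent lists of these sizes.

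The last comparison asks whether the response to EGF differs between genotypes. Enpp6 alone passed, at 3.50 ± 0.29 (adjusted p = 0.000147), with an EGF effect of -3.52 ± 0.19 in Cic+/+ and -0.02 ± 0.22 in Cic-/-, where it lay close to the dim limit in both media (4.54 ± 0.22 and 4.56 ± 0.49). The largest p on leaving out 1 clone was 0.00451, without clone 2. With the brightest probeset Enpp6 was at 2.58 and did not pass (adjusted p = 0.356), and with the lowest 50% of genes left out as dim it was not tested, since its mean of 5.81 lies under that limit of 5.93. At an unadjusted p under 0.05 there were 497 genes. Without clone 1, 4 or 7 the number passing was 2, 3 and 2, and 7 passed with the clone as a block, Enpp6 among them.

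The myelinating oligodendrocyte genes differed as a group. Of 12, 1 passed over all genes tested and 6 adjusted over the list alone, with 11 of 12 positive and a median interaction of 0.96 (camera adjusted p = 5.88e-17; adjusted p = 0.00039 with an estimated correlation). With the clone as a block 3 of the 12 passed. Mag was at 2.41 (adjusted p = 0.0874), a size that is not exact since its Cic-/- levels of 4.30 and 4.33 lie under the dim limit, Mbp at 1.74 ± 0.45, Cldn11 at 1.58 and Myrf at 1.54 ± 0.30, none of the 4 passing over all genes tested.

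Mitosis genes had a median interaction of -0.49, with 26 of 26 negative, 0 passing, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 1.71e-05; adjusted p = 0.734 with an estimated correlation). DNA replication genes had a median of -0.33, with 0 of 29 passing, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.00216; adjusted p = 0.736 with an estimated correlation; 0.109 and 0.0817 without clones 5 and 7). Target genes of p53 had a median of 0.33, with 0 of 16 passing, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.00197; adjusted p = 0.53 with an estimated correlation; 0.0566 without clone 5). Extracellular matrix genes had a median of 0.35 (camera adjusted p = 0.0134; adjusted p = 0.554 with an estimated correlation; 0.0755 without clone 5) and FoxO targets of 0.14 (camera adjusted p = 0.0228; adjusted p = 0.734 with an estimated correlation; 0.0563, 0.191, 0.592 and 0.0871 without clones 2, 4, 5 and 7). In these lists 0 of 16 and 0 of 20 passed, 0 adjusted over the list alone, and 0 and 1 had an unadjusted p under 0.05. Astrocyte genes had a median of 0.31, with an adjusted p of 0.0629 by camera, 0.0389 on the fit with the clone as a block and 0.554 with an estimated correlation. The interactions of Etv1 (-1.45 ± 0.41) and Pdgfra (-2.05 ± 0.54) did not pass (adjusted p = 1 for both).

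**Figure D4:**
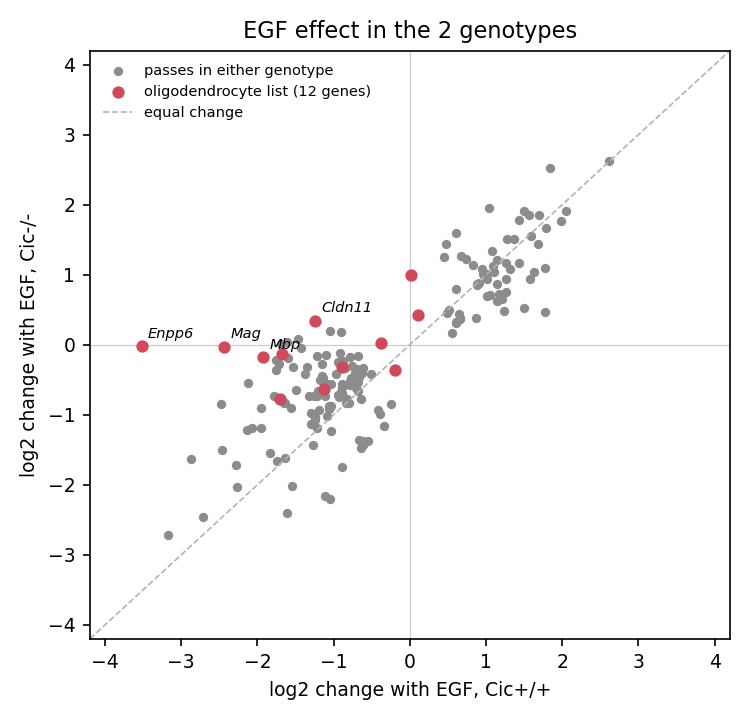
EGF effect in Cic-/- against that in Cic+/+, both in log2, for genes passing in either genotype and for the 12 myelinating oligodendrocyte genes. Enpp6 lies at -3.52 in Cic+/+ and -0.02 in Cic-/-, while Dgkk lies at 2.62 and 2.63.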

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

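The tests of the single-probeset pattern and the oligodendrocyte pattern, including the slope without Enpp6 and Mag, and the test of noise in the Cic probesets, were chosen only after the result was seen, while the test of a general shift of clone 6 and the splits of the arrays were chosen before.

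Many single probesets that passed between genotypes stood apart from their gene. Counting only genes with concordant probesets left 47 of 55 genes with EGF and 88 of 96 without. A gene with a single probeset, such as Mir139, has no other probeset to disagree with. That count therefore does not show how many gene calls rest on probesets that stand apart. The next test used only genes with at least 3 probesets above the dim limit. Of their probesets that passed between genotypes, 37.3% stood apart from the rest of their gene, against 7.16% in the EGF comparisons (Fisher exact p = 1.65e-31). That test counts probesets of the same gene, those of Cic included, as independent, so its p does not measure a spread over genes or animals. Genotype calls were not enriched around Cic, with 0.75% of its 400 neighbours called, namely Eid2b, Mag and Sirt2, against 0.696% of other genes (Fisher exact p = 0.759). This argues against a stretch of chromosome carried along with the Cic allele that changes many of these neighbours. A shorter stretch, or one acting on single probesets rather than gene values, could not be seen with so few calls and stays open. Sequence differences under the probes between animals remain a candidate explanation, as they would act on single probesets between animals and cancel between media of the same animal. The strain background is not given in the sources used here, so this stays open.

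Oligodendrocyte genes without EGF were lower in Cic-/-, and their EGF effect differed between genotypes, with an interaction of 3.499 for Enpp6 and a list median interaction of 0.9579, though Ugt8a, Cnp, Aspa and Mobp, 4 of the 12, were lower with EGF in every Cic-/- clone. Over 144 other called genes the slope of the Cic-/- response on the Cic+/+ response was 0.679, with 95% limits of 0.608 and 0.747. These genes were picked for passing in Cic+/+, which can lower the slope. It cannot decide whether the Cic-/- clones responded more weakly overall. The slope of the oligodendrocyte list was lower, at 0.0862, with an upper limit of 0.273. It was 0.196, with an upper limit of 0.429, without Enpp6 and Mag, which lie near the dim limit in Cic-/-. In Cic-/- without EGF, Mal (4.50 to 4.71) and, in clones 5 and 6, Opalin (4.10 and 4.28) also lay near that limit and were kept. The list was picked for its interaction, which itself lowers its slope. The slopes describe a smaller response of that list than of the other called genes. They cannot decide whether a weaker response of equal size in all genes is the whole account of that list. The limits resample genes and leave out the spread between clones. Fewer progenitors in the Cic-/- cultures stays open. Without EGF the progenitor list had a median of -0.0362 with limits of -0.55 and 0.13. These overlap the limits of the myelinating list at -2.43 and -0.19. With EGF the progenitor list had a median of -0.17 and was lower in 3 of 3 Cic-/- clones. Camera gave it an adjusted p of 0.00282 there, and 0.492 with an estimated correlation. An effect of the loss of Cic itself and other differences between the animals were not tested apart.

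Clone 6 was lower than the other Cic-/- clones over most of a run of Cic probesets and higher over later ones. A general disturbance of its arrays that parts the probesets of many genes was argued against. Of 8064 genes, 0.0124% had a run of 6 probesets as low against the rest of their gene, the only 1 being Cic. A uniform shift of the arrays cancels in this difference within a gene, so it was not tested here. Noise of single probesets was argued against by a correlation of 0.888 between the media. What made the clone differ was not tested and stays open.

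The real grouping of the arrays gave 55 genes with EGF against 1 in the highest of the other splits, and 96 against 15 without EGF. In both, 1 of 35 splits called as many, the smallest share possible and under 0.05. This argues against chance without excluding it. Both comparisons use the same clones, so these are not 2 independent results. For EGF in Cic+/+ it gave 156 against 5, also 1 of 35 splits, but the arrays are paired by clone, and the 8 splits that part every pair, with a highest other count of 0, are too few for a share under 0.05. For EGF in Cic-/- the 10 splits are too few for a share under 0.05, and the 33 genes stood against 1188 in the highest other split, 2 of 10 splits calling as many. That split set clone 5 in both media with clone 6 without EGF, so it points to structure of the samples, while the highest other count among the 4 splits that part every pair was 0. For the interaction the highest other count was 1, equal to the real 1, with 2 of 35 splits calling as many, and chance cannot be excluded.

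Of 174 groups of 4 arrays tested with Dixon's ratio, 20 or 11.5% held a value standing apart, and chance does so in about 1 in 20 groups. Groups of 3 arrays were not tested. Xist at 4.729 and 3.83 and the Y-linked Eif2s3y at 8.601 and 8.929, Kdm5d at 8.472 and 8.751 and Uty at 7.997 and 8.397 stood apart in clone 4 with and without EGF, because that clone is male by these genes. With EGF, Adamts16 at 5.85 in clone 2, Khdrbs2 at 5.53 in clone 4, the Notch pathway list at 8.395 in clone 3 and the housekeeping list at 10.77 in clone 1 stood above their group, and the cause was not tested. Without EGF, Pdgfra at 9.321 and F2rl1 at 6.595 in clone 3 and Etv4 at 7.895 in clone 1 stood below their group, and the cause was not tested. Etv5 at 11.51, Fbn2 at 8.441 and the EGF receptor family list at 7.825 stood above theirs in clone 1, the axon guidance list at 7.824 below in clone 1, and the ependymal list at 5.357 above in clone 3, again with no cause tested.

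Among the 21428 bright probesets with several gene symbols or none, 47 passed between genotypes with EGF, 89 without EGF and 13 for EGF in Cic+/+, and they were left out because they name no single gene.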

How the results depend on the processing

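The counts moved with the way probesets were combined. The mean over probesets gave 170 genes for the genotype effect without EGF, 256 for EGF in Cic+/+, 70 for EGF in Cic-/- and 2 for the interaction, all higher than in the main analysis. Each probeset on its own gave 160 and 267 genes for the genotype effect with and without EGF and 53 for EGF in Cic-/-. The brightest probeset gave 0 for the interaction by limma, with 429 at an unadjusted p under 0.05, and it turned the sign of 4 named results. These were Dysf (-0.17) and Eif2s2 (0.55) between genotypes with EGF, Fa2h in Cic+/+ (0.19) and Mapk8ip2 in Cic-/- (0.11) with EGF, and the cause was not tested.

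For EGF in Cic-/- the stricter dim filter gave 51 genes, the trended prior 50, centred arrays 55 and quantile normalization 59. The stricter dim filter gave 0 for the interaction by limma, with 215 at an unadjusted p under 0.05. With only the arrays compared there were 39 genes between genotypes with EGF, 29 of them among the 55. Without EGF there were 44, of which 42 were among the 96. Between genotypes this alternative leaves out the arrays of the other medium. It gave 3 genes for EGF in Cic-/- and is not defined for the interaction. The clone as a random block gave 897 genes for EGF in Cic+/+, 361 in Cic-/- and 7 for the interaction, and as a fixed block 969, 519 and 3. Beyond the genes and lists given with these blocked values, the random block changed no other call of a named result.

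Leaving out 1 clone gave 21 (clone 2) to 52 (clone 1) genes between genotypes with EGF, with 32, 25, 24, 33 and 26 without clones 3 to 7, and 63 (clone 5) to 109 (clone 7) without EGF. It gave 17 (clone 2) to 147 (clone 1) for EGF in Cic+/+, with 34 and 38 without clones 3 and 4, and 0 (clones 5 and 6) to 18 (clone 7) in Cic-/-. The interaction ran from 1 to 3 (clone 4), with 2 without clone 1 or 7. The change of Cic ran from -2.03 to -1.90 with EGF and from -2.27 to -2.05 without.

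The number of lists passing by camera ran from 5 to 9, 3 to 7, 10 to 13, 6 to 10 and 5 to 7 in the 5 comparisons in order, with 4 without clone 2 and 3 without clones 3 and 5 in the second. With an estimated correlation 0, 1, 2, 0 and 1 lists passed, against 7, 7, 12, 7 and 6, with 1, 2, 9, 5 and 2 at an unadjusted p under 0.05. Fry gave 0, 1, 8, 4 and 1, with 2, 4, 10, 7 and 1 unadjusted. Over all alternatives, 360 gene results gave 5040 values with the same call, 237 weaker, 37 stronger and 4 reversed. For 135 list results these were 1027, 103, 31 and 0. A result that passed in neither analysis counts as the same call, so these totals do not measure how often a passing call held. In the main analysis 17, 22, 26, 16 and 1 of the gene results passed in the 5 comparisons in order. With an estimated correlation 35 list results were weaker and 100 the same.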

Other observations

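The clustered protocadherins were looked at by family, without a test of the families as sets. Of 22 Pcdhb genes, which give neural cells distinct surface identities, 19 had a positive difference in Cic-/- with EGF and 18 without, with medians of 0.68 and 0.64. Pcdhb2 and Pcdhb3 passed in both media, and 10 had an unadjusted p under 0.05 in each. Of 14 Pcdhg genes 5 and 4 were positive, with medians of -0.65 and -0.84. None of these 14 passed by limma, and at an unadjusted p under 0.05 there were 1 higher and 4 lower with EGF and 1 higher and 6 lower without. The signs of these medians were the same with centred arrays (0.71 and 0.68 for Pcdhb, -0.62 and -0.80 for Pcdhg). The families were chosen after their values were seen.

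Part of the response to EGF was shared by the genotypes. Dgkk, Angptl2, Itga4, Kcnip1, Chrm3 and Psrc1 rose in both, and Gpr17, Pla2g7, Khdrbs2, Sh3bp4 and Tmem255b fell in both. With the brightest probeset, Itga4, Kcnip1, Psrc1, Pla2g7, Khdrbs2 and Sh3bp4 lost their call in Cic-/-, with Khdrbs2 at -0.35. With the clone as a block 93 genes rose and 106 fell in both genotypes, where 3.43 and 5.98 would be shared by independent lists of these sizes, and 0 moved in opposite directions.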
